A study of Oryza sativa with 2 samples.

How the data were processed

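Small RNA was sequenced from panicles (flowering branches) of rice, Oryza sativa ssp. japonica cultivar Zhonghua 11, grown in a paddy field. There were 2 libraries, 1 from wild type and 1 from a mutant edited with CRISPR-Cas9 in the genes DDM1a and DDM1b, the rice copies of DDM1, a chromatin remodeler needed to keep DNA methylation on heterochromatin. Per the labels' protocols, RNA was extracted with TRIzol and precipitated in ethanol overnight, and libraries were made with a Vazyme small RNA kit for an Illumina HiSeq instrument. For each library the authors deposited a list of distinct sequence tags with a raw count for each tag, not scaled to depth. The submitters' processing notes name cutadapt 4.8. Other filters, an aligner and a genome build are not given in the sources used here.

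Tag lengths ran from 18 to 30 nt. The library totals were 2249822 reads over 163159 distinct tags in wild type and 1956900 reads over 235047 distinct tags in ddm1. An uneven feature of the counts set the error model: 86.9% of wild-type tags and 87.8% of ddm1 tags had an even count, and 95.4% and 95.6% of those with counts from 4 to 19 did. Most inserts thus appeared 2 times in the counts, as paired reads of 1 fragment would. Intervals were therefore computed on reads divided by 2, and the floor for an absent tag was set at 3 inserts, or 6 reads, which is 2.67 RPM in wild type and 3.07 in ddm1. Tags with an undetermined base held 0.186% and 0.312% of reads and stayed in the totals.

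Before the data were examined, the comparisons, their thresholds, the alternatives and a list of 30 rice microRNA families were fixed for loci or, failing loci, for tags. As the values were counts per tag, each tag took the place of a locus. Abundance was given in RPM, reads per 1000000 deposited reads of the library. A tag was compared when it reached 10 RPM in the higher library, and was called higher or lower at a fold of 2 or more, with counts under 6 reads set to 6. Shares carry exact Clopper-Pearson 95% intervals. Folds carry 95% intervals from the exact binomial distribution of 1 library's inserts given the sum of both. A microRNA family was the sum of tags that hold positions 2 to 18 of a listed mature sequence. The median fold of the families was placed among 10000 random lists of single tags, each drawn from the 200 tags nearest in mean abundance, and its interval came from 2000 Poisson draws of the inserts.

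Several partitions were chosen only after the tags had been examined. Tags sharing 16 nt were joined into overlap groups. Groups holding 16 nt of any of 14 conserved plant ribosomal RNA stretches were called ribosomal; 13 of the stretches were found, and the groups held 55274 tags. Tags of 20 nt or more were translated in all frames of both strands and matched to Streptococcus pyogenes Cas9 (SpCas9, 1368 residues) and to hygromycin phosphotransferase (HPT, 341 residues, a common plant selection marker), requiring at least 6 residues with no mismatch. The same proteins read backwards served as a control. Tags were also matched to the first 12 nt of 34 animal microRNAs, with 100 shuffled lists as a control, and to the terminal repeats of 2 families of miniature transposons. The ribosomal, animal and transposon sequences and both proteins were written from general knowledge with no database, so few or no matches can also reflect the sequence listed. Overlap groups of at least 5 tags outside the ribosomal, transgene and animal sets were assigned to a size class when 1 length held at least 50% of their reads.

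The text names, by a rule fixed in advance, the 10 most abundant listed microRNA families together with miR2118, miR2275 and miR820. It also covers the 5 largest falls and 5 largest rises among tags found in both libraries, the 3 most abundant tags found in 1 library only, and the 5 most abundant 24-nt tags of wild type. Sequences are printed only for rice microRNA and for ribosomal tags, since a tag of unknown origin can come from another organism.

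The rule of size was tested on simulated data drawn from 8820 real tags of the ddm1 against wild type comparison with known changes. It recovered 95.8% of 48 tags raised 3-fold, 100% of 23 raised 4-fold and 100% of 31 raised 8-fold. Of tags lowered 3-, 4- and 8-fold it recovered 80%, 81.2% and 90.3%, and it called 4.25% of 8620 unchanged tags. The simulation held counting noise only, with no difference in background between the libraries. These values are therefore no error rates for the calls in the real libraries. The translated match recovered 100% of 500 simulated SpCas9 tags and took 0.02% of 20000 random tags. The simulated tags were exact back-translations of the listed protein, so their recovery was fixed in advance and does not measure sensitivity on real tags.

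Alternatives covered the abundance minimum (2 and 50 RPM), the fold (1.5 and 4), scaling by listed microRNA reads or by the median ratio of shared tags, whole-sequence microRNA matching, distinct tags in place of reads, and removal of the 10 most abundant tags. Comparisons by repeat or gene class, by chromosome region and by phased or hairpin locus were not run, because the tags carry no coordinates and no genome was used here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.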

Results

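DDM1 keeps transposons and other heterochromatin methylated and silent, and the series asks which small RNA of the rice panicle depends on it. A library of wild-type panicles (2249822 reads) was set against a library of ddm1 panicles (1956900 reads). With 1 library per genotype there is no replicate check and no p-value; the differences describe these libraries, and intervals and floors cover counting error only. The small RNA tags do not report on the edited DDM1 genes themselves. The libraries shared 31953 tags, which held 80.9% of wild-type reads and 53.4% of ddm1 reads.

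The libraries differed widely in the share of ribosomal RNA fragments, the breakdown products of the RNA of ribosomes. Ribosomal overlap groups held 76.5% of wild-type reads (95% interval 76.4 to 76.5) and 30.6% of ddm1 reads (30.6 to 30.7). The intervals cover counting error only. The groups are chains of tags that share sequence, not alignments to ribosomal RNA. When 17 nt had to be shared, more 22-nt reads fell outside ribosomal and transgene tags. They rose from 45829 to 78054 in wild type and from 127879 to 137642 in ddm1. The ribosomal shares thus depend on the overlap rule, and their values with 17 nt are not given here. The largest single group held 74.8% and 27.3%. The ends of these fragments also differed, as 73.3% of ribosomal reads in wild type ended in A against 32.8% in ddm1, or 43.5% against 26.8% when each distinct tag counted once. Outside ribosomal and transgene tags, reads ending in A made up 45.1% of wild type and 19.8% of ddm1. Any abundance given in RPM, reads per 1000000 of all reads, was therefore measured against a background that differed between the genotypes. Relative to all reads, scaling to listed microRNA reads shifted every log2 fold by -2.02. Scaling to reads outside ribosomal and transgene tags shifted it by -1.37, a value that depends on the overlap rule. Scaling to the median ratio of shared tags shifted it by -0.20. This last shift equals the log2 ratio of the ddm1 to the wild-type read total. It therefore only undoes the scaling to depth and gives no separate measure of the background.

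The ddm1 library held many tags that encode stretches of 2 proteins typical of an editing transgene. Tags encoding SpCas9, the nuclease of the CRISPR system, made up 7.80% of ddm1 reads (152630 reads, 6268 tags), and those encoding HPT, the hygromycin resistance marker, 0.626% (12243 reads). In wild type these proteins had 556 and 54 reads. Reversed proteins, the background of the match, gave 78 reads in wild type and 34 in ddm1. The SpCas9 tags of ddm1 reached 1276 of the 1368 residues and the HPT tags 314 of 341. Of the SpCas9 reads, 72.8% were 21 nt, 16.7% were 22 nt and 2.92% were 24 nt long, and 70.7% (70.4 to 71.0) were antisense to the coding strand. HPT reads were 63.3% 21 nt and 31.1% (29.97 to 32.3) antisense. Coverage was uneven: tags that began at residues 1 to 120 of SpCas9, 8.77% of the protein, held 38 reads, or 0.0249% of its total, and a single tag held 19.5%.

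**Figure D1:**
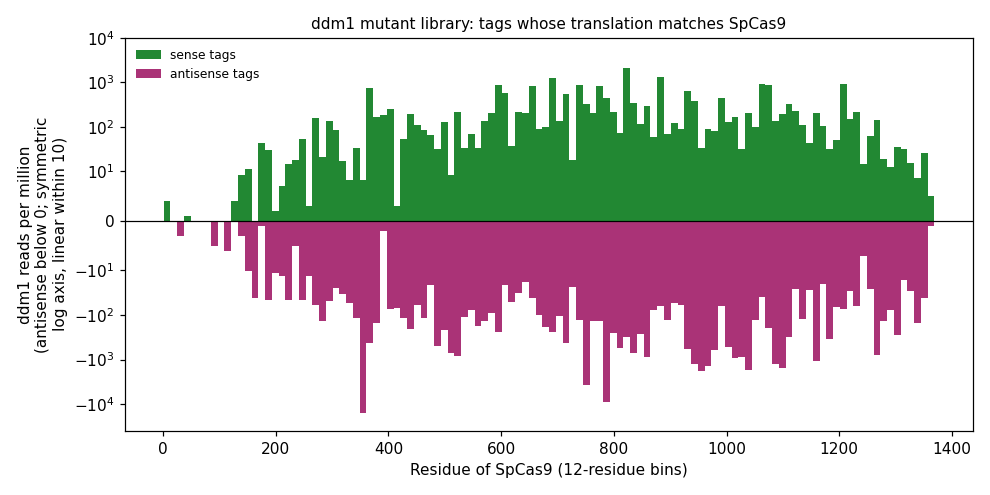
RPM of the ddm1 library (vertical axis, symmetric log, linear within 10) along SpCas9 (horizontal axis, residues, bins of 12) for sense tags above 0 and antisense tags below 0; each bar sums the tags that begin in the bin, 1 library. The tallest antisense bin, residues 349 to 360, reached 15783 RPM, and the first 120 residues were nearly empty.

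In plants 21-nt and 22-nt small RNA mainly guides RNA cleavage and 24-nt small interfering RNA guides DNA methylation, so the length profile was compared first. In all deposited reads each of these lengths had a higher share in ddm1. The 21-nt share was 12.8% in wild type and 17.03% in ddm1, the 22-nt share 8.12% and 10.8%, and the 24-nt share 11.9% (11.85 to 11.97) and 14.3% (14.2 to 14.4). The direction at 21 and 24 nt rested on which RNA was counted. Without transgene tags the 21-nt share was 12.8% in wild type and 11.96% in ddm1, and without ribosomal groups as well it was 12.1% and 12.8%. Without ribosomal groups the 24-nt share was 21.01% and 16.7%, and with ribosomal and transgene tags both left out it was 21.03% and 18.6%. The 22-nt share stayed higher in ddm1 in each of these sets, at 8.67% and 10.7% with both left out. When 17 nt in place of 16 had to be shared within an overlap group, the 24-nt share without both sets was again higher in ddm1, by 1.01 percentage points, and the 22-nt gap narrowed from 2.06 to 0.534 points. Tags that begin like animal microRNAs, 24336 reads in ddm1 and 1359 in wild type, were not left out of these shares. They also stayed in the sums by length below. Their part in the 22-nt gap was not measured.

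**Figure D2:**
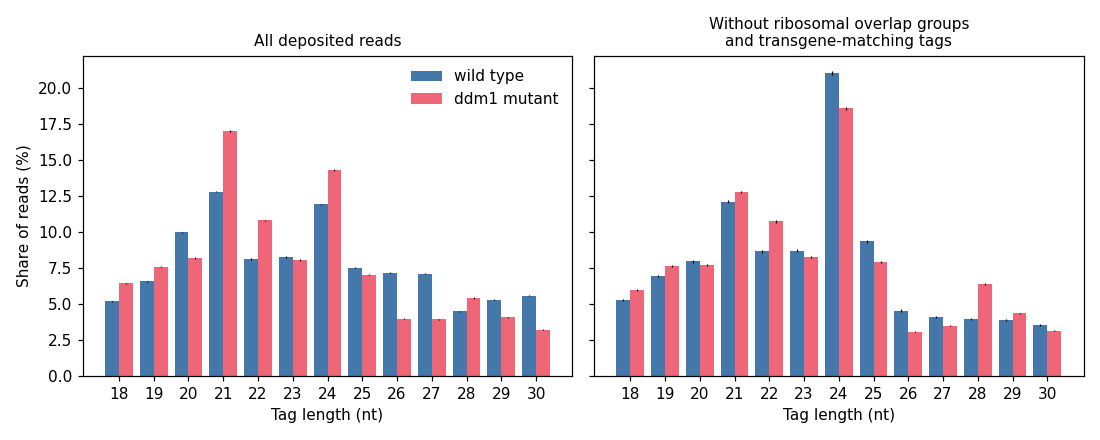
Share of reads (vertical axis, %) by tag length (horizontal axis, nt) in wild type (blue) and ddm1 (red), 1 library each, for all reads (left) and without ribosomal groups and transgene tags (right); black lines are exact 95% intervals of counting error. At 24 nt the order changes from 11.9% and 14.3% on the left to 21.03% and 18.6% on the right.

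Summed 24-nt reads outside both sets had no direction independent of scaling. There were 111217 in wild type and 221595 in ddm1, which is 2.29-fold higher in ddm1 per read deposited. It is 0.884-fold (0.875 to 0.893) per read outside ribosomal and transgene tags, which turned to 1.06-fold when groups had to share 17 nt, and 0.565-fold (0.533 to 0.598) per listed microRNA read. The 21-nt reads had folds of 2.73, 1.05 and 0.674 on these 3 scales and the 22-nt reads 3.21, 1.24 and 0.791. With 17 nt shared, the 22-nt folds were lower, at 2.03, 1.05 and 0.50. Assembled into overlap groups, a stand-in for loci chosen after the tags were seen, the 24-nt class had 1940 groups. Of these, 1301 were higher and 19 lower in ddm1 per read deposited, 269 higher and 281 lower per read outside ribosomal and transgene tags, and 63 higher and 657 lower per microRNA read. Their sums were 2.82-fold, 1.09-fold and 0.695-fold on these scales, with median log2 folds of 1.42, 0.05 and -0.60. Groups of no single class, 4908 in number, summed to 2.48-fold, 0.955-fold and 0.611-fold, with medians of 1.56, 0.19 and -0.46. The 201 groups of the 22-nt class summed to 9.42-fold, 3.63-fold and 2.32-fold higher in ddm1 on the same scales, while their median log2 folds were 1.94, 0.56 and -0.08. The 287 groups of the 21-nt class summed to 1.89-fold, 0.728-fold and 0.466-fold, with median log2 folds of 1.79, 0.41 and -0.23, so sum and median differed in direction on the second scale. Without a genome, no group was placed on a chromosome or shown to come from rice.

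Distinct tags, the finest unit the counts allow, numbered 163159 in wild type and 235047 in ddm1, a ratio of 1.44. Outside ribosomal and transgene tags and with ddm1 thinned to the wild-type read number there, the ratio was 0.967. Of 14316 tags compared, 7549 were higher and 4800 lower in ddm1 by the rule of size. Ribosomal groups supplied 3731 of the lower tags (77.7%) and 2562 of the higher ones, and SpCas9 or HPT supplied 939 of the higher ones. The split moved with the scale and the tag set. Per listed microRNA read 888 tags were higher and 6438 lower. With the median ratio, which here compares counts without scaling to depth, 5937 were higher and 5008 lower. With ribosomal and transgene tags left out and RPM unchanged, 4048 were higher and 1069 lower.

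Among 24-nt tags 1016 were higher and 395 lower in ddm1, and 301 of the lower ones were ribosomal. Scaling to microRNA reads gave 51 and 582. Leaving out ribosomal and transgene tags gave 789 and 94. Among 21-nt tags 1362 were higher and 401 lower, with 569 of the higher ones encoding SpCas9 or HPT. The corresponding pairs were 250 and 560 on the microRNA scale, and 535 and 105 without ribosomal and transgene tags. Among 22-nt tags 916 were higher, 230 of them encoding SpCas9 or HPT, and 418 lower, and in that order the pairs were 118 and 560, and 447 and 104.

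The 5 largest falls among tags of both libraries were all ribosomal. Their ddm1 counts were 2 to 6 reads, so their order and the size of the folds are uncertain. AATGAGAACTTTGAAGGCCGAAGA had 538 RPM in wild type and 2 reads in ddm1, a ratio of 526 (94.1 to 20819), or 175 with the ddm1 count set to the floor. With counts set to the floor, the other 4 were 165-fold to 385-fold lower in ddm1, and AATCGTTCGTCTGACTTGGGTATA, at 6 ddm1 reads, had the largest fold of the 5 (385-fold, 132 to 1872). The 3 most abundant tags of wild type with no ddm1 read were ribosomal too, led by TCGATCCTTTAGACCTTCGGAGTTTGAA at 317 RPM, 103.5-fold above the ddm1 floor. Of the 5 largest rises, 1 was an antisense SpCas9 tag over residues 756 to 761, at 6.22 RPM in wild type and 3051 in ddm1, 490-fold higher (238 to 1221). The other 4 matched none of the sets used here; the first, 28 nt long, had 5.78 RPM in wild type and 21656 in ddm1. Their organism of origin was not determined, and such tags stayed in the totals, size shares and group counts. The 3 most abundant tags with no wild-type read were also without a match, at 2467, 929 and 924 RPM, which is 925-, 348- and 347-fold above the wild-type floor. Chosen on wild-type counts, which leans towards lower values in ddm1, the 5 most abundant 24-nt tags of wild type were ribosomal. All were lower in ddm1, by 6.85-fold to 145-fold. The first, CTCTAGTCCGACTTTGTGAAATGA, had 19718 RPM in wild type and 1035 in ddm1.

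MicroRNA families, which guide cleavage of regulatory messenger RNA, were mostly higher in ddm1 per read deposited. Per read outside ribosomal and transgene tags their median was far smaller and few were called, in both directions. Of 30 listed families 25 were detected and 17 compared; 15 were higher in ddm1 and 0 lower. The median log2 fold was 1.91 (1.49 to 2.08), at percentile 92.4 of random lists of tags of like abundance. Those lists, with a median of 0.27, drew on ribosomal and transgene tags too. The percentile is therefore not free of the difference in ribosomal share. Per read outside ribosomal and transgene tags the median of the same 17 families was 0.53, and it was 0.24 over the 21 families that passed the minimum on that scale. Of those 21, 2 were higher and 3 lower, on a scale whose floor favours calls of lower. Among random lists drawn only from tags outside both sets, the median of the 21 lay at percentile 88.5. Those lists had a median of -1.11 on that scale, which the same floor can lower. Scaling by the listed microRNA reads centres the families by construction and gave a median of -0.11 over the 17.

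The most abundant family was miR159, a regulator of GAMYB transcription factors, at 581 RPM in wild type and 2568 in ddm1 (4.42-fold, 4.05 to 4.82). The HD-ZIP III regulator miR166 followed at 425 and 1360 (3.20-fold, 2.88 to 3.56). Of the 10 most abundant families, miR156, which restrains SPL transcription factors and adult traits, stood furthest apart, at 24 and 632 RPM. It was 26.3-fold higher (17.9 to 40.3), and 10.2-fold higher (6.91 to 15.5) per read outside ribosomal and transgene tags. Next came miR319, a regulator of TCP factors, at 80.9 and 304 RPM, and miR167, a regulator of auxin response factors, at 107 and 250. Regulators of the small RNA machinery were miR168, which targets AGO1, at 18.7 and 103 RPM, and miR162, which targets DCL1, at 24.9 and 76.1. The MADS-box regulator miR444 had 25.8 and 54.7 RPM, the growth-regulating factor regulator miR396 in its listed form had 11.6 and 48.0, and miR394 had 8.89 and 43.9. Per read outside ribosomal and transgene tags, miR156, miR159 (1.71-fold, 1.56 to 1.86), miR168 (2.13-fold, 1.32 to 3.59), miR319 (1.45-fold, 1.14 to 1.85) and miR166 (1.23-fold, 1.11 to 1.37) had intervals above 1. The intervals of the other 5 spanned 1, with miR167 at 0.900-fold (0.722 to 1.13) and miR444 at 0.818-fold (0.517 to 1.35). Folds on this scale used groups sharing 16 nt and were not recomputed with 17 nt, where summed 24-nt reads turned from 0.884-fold to 1.06-fold. With 17 nt the folds on this scale would be higher, so families below 1 could rise above it and more could reach 2-fold. Relative to the listed microRNA reads as a whole, a scale on which some families must lie below 1, miR156 was at 6.49-fold. Outside ribosomal and transgene tags the libraries also differed in reads ending in A (45.1% in wild type, 19.8% in ddm1). Whether the last nucleotide of a family shaped its fold was not tested. The miR396 value rests on a rare form: a variant outside the list had 278 and 919 RPM, and both forms together were 3.34-fold per read deposited and 1.29-fold (1.13 to 1.46) per read outside ribosomal and transgene tags.

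Of the triggers of reproductive phased small RNA, miR2275, which starts the 24-nt kind, had 20 reads in wild type and 52 in ddm1 (2.99-fold, 1.39 to 6.95; 1.15-fold, 0.538 to 2.68, per read outside ribosomal and transgene tags; 0.737-fold per listed microRNA read). The trigger of the 21-nt kind, miR2118, had 4 and 0 reads in its listed form, so no difference was detectable at this depth. No read of the listed form of miR820, a microRNA carried by a transposon, was found in either library. That allows up to 2.67 RPM of this form in wild type and 3.07 in ddm1. Forms outside the list, which for miR396 were the more abundant, were not counted for these families.

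**Figure D3:**
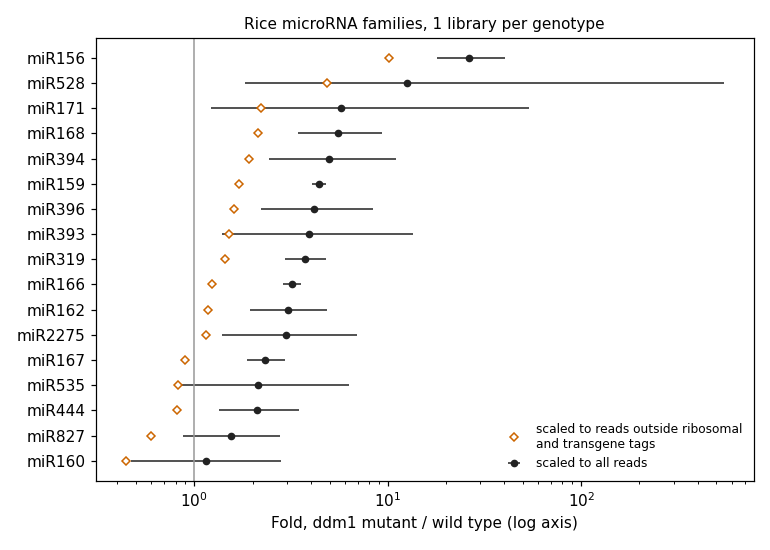
Fold of 17 compared microRNA families, ddm1 over wild type (horizontal log axis), 1 library per genotype; black points are scaled to all reads with 95% intervals of counting error, and open diamonds to reads outside ribosomal and transgene tags. On the first scale miR156 lies highest at 26.3; on the second it lies at 10.2 and miR167, miR535, miR444, miR827 and miR160 lie below 1.

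The first nucleotide helps sort small RNA among Argonaute proteins, with U favoured by AGO1 and A by AGO4. Among 21-nt reads, U came first in 35.7% (35.5 to 35.9) of wild type and 58.9% (58.7 to 59.2) of ddm1. The gap held without ribosomal and transgene tags, at 39.3% and 59.7%. It narrowed when each distinct tag counted once, to 46.2% against 53.0% over all tags and 50.8% against 57.3% without both sets. Among 24-nt reads, A came first in 34.4% of wild type and 43.0% of ddm1. That order turned without ribosomal groups, to 49.1% (48.6 to 49.5) and 47.4% (47.1 to 47.7), and by distinct tags, to 49.2% and 45.8%.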

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

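All tests in this part were chosen after the results they address had been seen. Signals outside the planned comparisons drew attention in 2 places: tags encoding SpCas9 or HPT, at 84252 RPM in the ddm1 library, and tags that begin like animal microRNAs, at 12436 RPM in the same library. Wild type held 271 and 604 RPM of them.

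The 21-nt share of reads was higher in ddm1 by 4.22 percentage points. Ribosomal fragments as the reason are argued against, since leaving out their groups widened the gap to 7.79 points. Without tags encoding SpCas9 or HPT the change was -0.830 points, so a candidate explanation is that small RNA from an editing transgene, whose presence is inferred from these tags, made most of the difference. With ribosomal groups out as well, 0.655 points stayed (2.34 with groups sharing 17 nt). The match covered only SpCas9 and HPT, so small RNA from other parts of such a transgene would have stayed in that remainder. Whether it or an effect of the ddm1 genotype made the remainder is open and untested. Whether loss of DDM1 alters silencing of such a transgene was not tested.

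The 24-nt share of reads was higher in ddm1 by 2.37 points. Small RNA encoding SpCas9 or HPT as the reason is argued against, as the gap grew to 3.41 points without it. Without ribosomal groups the change was -4.32 points (-0.713 with groups sharing 17 nt), so the larger share of ribosomal fragments in wild type may account for the order seen in all reads. With transgene tags out as well the change was -2.45 or, with 17 nt, 1.01 points, so the direction of any 24-nt change in ddm1 is not fixed by these libraries. RNA breakdown or size selection that differed between the preparations stays open, as does the genotype.

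Tags that begin like animal microRNAs were found for 12 of 34 listed names with at least 20 reads in ddm1 and for 9 in wild type, where shuffled lists gave at most 1, which argues against chance matches. Carry-over of ddm1 reads into the wild-type library is argued against as the whole source there, because bantam-like reads of wild type were 3.46% (3.05 to 3.91) of the ddm1 level and transgene reads 0.322% (0.287 to 0.360). A single animal that contributed the same mix of microRNAs to both libraries is argued against too, as folds between the libraries, among the 10 listed names with at least 100 reads, ranged over 29.1 times, from 1.32 (0.901 to 1.95) for miR-1-like to 38.5 (16.2 to 121) for miR-276-like reads. Material from more than 1 animal, or from different tissues of one, on panicles grown in the field may be the source and was not tested. No biological explanation from the design was tested.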

How the results depend on the processing

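Settings that leave out ribosomal groups or transgene matches, thin a library or use the rest as the total were chosen after the data were seen; the others were planned. Of 124 alternative values for 19 results, 38 stayed within a tolerance, 72 moved beyond it and 14 reversed. The tolerance was 1.5 times for a count of tags or families. For shares, ratios and medians it was a 95% counting interval of the reported value, which is mostly far narrower. A count has no sign, and none was labelled reversed, even where the split turned. With microRNA scaling, 7549 higher and 4800 lower tags became 888 and 6438. The number of reversals therefore leaves out such turns. No paired analysis was possible because each genotype has 1 library and the labels carry no replicate numbers, and no library could be left out. Joining loci only at a larger overlap, uniquely mapped reads, size purity of loci, repeat classes and phase scores were not run, as tags have no coordinates. Depth limits many tags: 59.4% of wild-type and 42.0% of ddm1 tags have a count of 2. Except where stated, the cause of a change was not tested.

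The change of the 21-nt share (4.22 percentage points) was 4.48 and 8.42 with minimums of 2 and 50 RPM, 5.18 without the 10 most abundant tags and 2.33 by distinct tags. It was 7.79 without ribosomal groups, -0.830 without transgene matches, 0.655 without both, 9.04 and 2.34 for ribosomal groups alone and for both with 17 nt shared, and 1.57 by distinct tags without both. In the same order, the change of the 22-nt share (2.68) was 2.81, 2.26, 2.88, 1.97, 2.81, 2.11, 2.06, 1.24, 0.534 and 1.63. The change of the 24-nt share (2.37) was 3.18, -2.90, 3.72, -1.46, -4.32, 3.41, -2.45, -0.713, 1.01 and -3.29. With 17 nt shared, the fold of 24-nt reads per read outside both sets (0.884) was 1.06, and those of 21-nt (1.05) and 22-nt reads (1.24) were 1.23 and 1.05.

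The ratio of distinct tags (1.44) was 4.42 and 0.852 with minimums of 2 and 50 RPM, 1.62 without ribosomal groups, 1.40 without transgene matches, 1.57 without both, and 1.61 with wild type thinned to the ddm1 total. It was 0.967 with ddm1 thinned to the wild-type total outside both, so the larger number of such reads in ddm1 accounts for its excess of tags there.

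Of tags higher in ddm1 (7549) there were 16101 and 1220 with the minimums of 2 and 50, 888 with microRNA scaling and 1950 without both sets and scaled to the rest. Of lower tags (4800) there were 1599 with the minimum of 50 and 8941 scaled to the rest. On that scale wild type has the smaller total, so a tag at the floor of 6 reads in both libraries is called lower; the counts scaled to the rest therefore carry no direction. In the order minimum of 2, minimum of 50, microRNA scaling and rest, the 24-nt tags higher (1016) were 2602, 86, 51 and 265, with 666 at a fold of 4. The 21-nt tags higher (1362) were 2666, 275, 250 and 237, and the 22-nt tags higher (916) were 1939, 148, 118 and 231. The 24-nt tags lower (395) were 610 with the minimum of 2, 143 with 50 and 2003 scaled to the rest. The 21-nt tags lower (401) were 131 with the minimum of 50 and 984 scaled to the rest, and the 22-nt tags lower (418) were 128 and 739. Without both sets but with RPM unchanged there were 4048 higher and 1069 lower tags, 94 lower at 24 nt, 535 higher and 105 lower at 21 nt, and 447 higher and 104 lower at 22 nt. All other alternatives for these counts lay within 1.5 times.

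The median log2 fold of microRNA families (1.91) was 1.48 with the median ratio, 0.24 scaled to the rest and -0.23 with microRNA scaling, which centres the families by construction. In each of these settings the set of families past the minimum changed along with the scale. Over the 17 families of the reported value the medians were 1.71, 0.53 and -0.11. The median ratio here amounts to counts not scaled to depth. Families higher (15) were 8 with the minimum of 50, 6 at a fold of 4, 1 with microRNA scaling and 2 scaled to the rest. Scaled to the rest 3 families were lower, against 0 on the reported scale. The change in 24-nt reads that start with A (8.61 points) was -3.34 by distinct tags, -1.70 without ribosomal groups and -1.54 without both. The change in 21-nt reads that start with U (23.2 points) was 6.75, 25.2 and 20.3.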

Other observations

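The lists in this part were chosen after the data had been seen, and the values are given without explanation. A common sequence variant of miR396, UCCACAGGCUUUCUUGAACUG, which the listed form does not match, had 626 reads in wild type and 1799 in ddm1. Per read deposited it was 3.30-fold higher in ddm1 (2.90 to 3.77), beside 4.16-fold for the listed form, and 1.27-fold higher (1.12 to 1.45) per read outside ribosomal and transgene tags. Terminal repeats of Stowaway, a family of miniature transposons common in rice, had 30 reads in wild type and 28 in ddm1, a fold of 1.07 (0.480 to 2.38) per read deposited. The fold was 0.414 (0.185 to 0.920) per read outside ribosomal and transgene tags and 0.265 (0.118 to 0.588) per listed microRNA read, so whether a difference is seen depends on the scale. Terminal repeats of Tourist, another such family, had 0 and 2 reads, too few to compare.

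Of the 5 most abundant 24-nt tags of wild type outside ribosomal groups, 2 were 28.9-fold (16.7 to 54.7) and 38.5-fold (17.5 to 106) lower in ddm1 per read deposited, while the other 3 had folds of 1.21, 0.886 and 1.73. Per read outside ribosomal and transgene tags these 3 were at 0.468, 0.342 and 0.666, so all 5 were lower in ddm1 on that scale. The 5 were chosen on their wild-type counts, which leans towards lower values in ddm1, so their direction does not speak for 24-nt tags in general. None of the 5 matched a set used here. The wild-type library held 176 tags that encode SpCas9 or HPT, and 143 of them, with 87.7% of their reads, were also in the ddm1 library. Animal-like reads were led in ddm1 by bantam-like (6815 RPM, against 236 in wild type), miR-315-like (3521 against 138) and miR-124-like (1281 against 107) tags.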
